A study of Mus musculus with 12 samples.

How the data were processed

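The series measured RNA in 3 mesenchymal mouse breast cancer cell lines: PyMT-1099 LT and Py2T LT, from tumours of MMTV-PyMT mice, and MT∆Ecad, from tumours of MMTV-Neu mice. Each line was transfected for 48 hours with an siRNA against Nrf2 (siNrf2) or with a non-targeting control siRNA (siCtl), both from Dharmacon, per the labels' protocols. Each of the 6 groups holds 2 replicates, which makes 12 libraries, and the series text calls the replicates biological. Total RNA (200 ng for the library kit) was depleted of ribosomal RNA and made into stranded libraries with an Illumina Ribo-Zero Gold kit, and single reads of 81 nt were sequenced on an Illumina NextSeq, per the labels' protocols. Reads were aligned with STAR to mm10, per the submitters' processing notes. Neither these notes nor the labels say which tool and annotation counted the reads, or whether the counting used the strand, so overlapping genes and close paralogs are uncertain where their reads could have been split.

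The authors deposited CPM, counts per 1000000 reads, for 24454 Entrez gene IDs in each library, and every column sums to 1000000. The smallest steps of these CPM values showed that whole reads had been counted: 100% of the values in each library came out as whole reads within a tolerance of 0.01 of a read. The totals recovered in this way lie between 27088970 and 37070635 reads per library, so a CPM of 1 stands for 27.1 to 37.0 reads. A gene without a read in a library has a CPM of at most 0.1107 there, taking 3 reads as the limit that a count of 0 allows, and this limit covers counting error only. Of the IDs, 24374 were matched to symbols of the RefSeq annotation of GRCm38.p6 and 6 more through GENCODE release M21, and 74 had no match. A single ID without a match held 0.641% to 1.462% of the reads of a library. The table held no reads of mitochondrially encoded genes, and 6189 genes were at 0 in all 12 libraries.

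Expression was compared as log2(CPM + 1), and every fold change is given on this scale, which understates the changes of genes with low values. Genes with a CPM of at least 1 in at least 2 libraries were tested, 12502 in all. A limma model (version 3.58.1 in R 4.3.3) with a mean for each of the 6 groups and an empirical Bayes variance with a mean trend was fitted to all 12 libraries, which leaves 6 residual degrees of freedom. Its contrasts were siNrf2 minus siCtl in each line, the mean of these 3 contrasts, which weights the lines equally, and the difference of the siNrf2 effect between lines (an F test, and each pair of lines). Tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The p-values measure the spread between these samples, in which each line is a single line and each group 2 cultures. SE is the standard error of a log2 fold change, and SD is taken over the 2 libraries of a group.

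Of 39 gene lists fixed from textbook knowledge, 38 had at least 3 tested members. The 15 mitochondrially encoded genes had 0 tested members. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The test was repeated with a correlation estimated from the residuals and with fry, which asks whether a list moves on balance and compares it with no other gene. The design, the lists, the threshold, the rule for named genes and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later. The rule names Nfe2l2, the 10 largest rises and falls of the average effect that keep their sign in each line, and the 5 largest rises and falls of each line whose siNrf2 libraries lie beyond both siCtl libraries. It also names the 5 smallest p-values of the difference between lines, the 4 largest called average changes of each list, and every tested NRF2 target gene. Genes with a mean CPM under 2 or without a proper symbol are not named. Genes named beside these are said to have been chosen after their values were seen.

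The replicate numbers are shared by the siCtl and siNrf2 groups, and the labels do not say what they mark. Deviations from the group mean of libraries with the same number correlated across genes within each line, with r of 0.778 in PyMT-1099 LT, 0.846 in Py2T LT and 0.625 in MT∆Ecad. The numbers were therefore taken to pair the siCtl and siNrf2 libraries of a line. A fit with the replicate number within each line as a block (6 pairs, 3 residual degrees of freedom) is called the blocked fit, and its value stands beside a result whose call it changes or whose count it moves by more than 1.5 times. Across lines, the same-number correlations lay between 0.558 and 0.792 for PyMT-1099 LT with Py2T LT and between −0.413 and −0.017 for MT∆Ecad with either of them. The replicates of a group differed by more than read sampling allows, with chi-squared values of 15.21 to 81.16 per gene at 1 degree of freedom.

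Alternatives changed the pseudocount, the filter, the scaling of the CPM (TMM or median-of-ratios factors), the variance model, the block, the threshold and the libraries in the fit. The fits with a library left out have no block and leave a pair incomplete, so the effect of the replicate number enters that line's log2 fold changes. What changes in such a fit can therefore not be told apart from this effect. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) called 13 genes in PyMT-1099 LT, 6 in Py2T LT, 1600 in MT∆Ecad and 856 on the average, and DESeq2 1.42.0 called 86, 33, 1864 and 1268 in the same order. The limma fit was tested on simulated counts of 12414 genes drawn from these libraries' means and totals without a replicate effect. Of changes of 2-fold it recovered 77% in PyMT-1099 LT, 63% in Py2T LT, 74.5% in MT∆Ecad, 94% in the average and 6% in the difference between lines. Of changes of 1.5-fold it recovered 11%, 13%, 24.5%, 64% and 0% in the same order, and 4.3%, 15.6%, 3.9%, 5.3% and 14.3% of its calls were false. In a second simulation of 12417 genes, with an effect shared by the libraries of a replicate number within a line, it recovered 28%, 24%, 44%, 97% and 0% of the 2-fold changes, and the blocked fit recovered 37%, 22%, 51%, 93% and 0%. Recovery in the average was counted only over genes changed alike in all 3 lines, without those changed in MT∆Ecad alone. Both simulations took each gene's spread from a fit without the block, so the spread shared within pairs entered as independent noise. They therefore cannot show how much the block gains in these data. DESeq2 made 14.7% to 45.7% false calls in the first simulation. 3′ UTRs of GENCODE M21 transcripts were searched for every 7-mer held by at least 100 genes, 15697 in all, and genes with and without each were compared by log2 fold change. This search was tested on simulated values in which all 5 planted 7-mers ranked first. ACCATTT and GAGAAGT, the 2 unrelated 7-mers most strongly tied to falling genes, are stated where a named gene's 3′ UTR holds them. For Il33 and Esr1 they are given as either 7-mer, without telling which. Other computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.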

Results

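RNA of 3 mesenchymal mouse breast cancer lines was sequenced 48 hours after transfection with siNrf2 or siCtl, to compare what loss of Nrf2, the transcription factor that drives antioxidant and detoxification genes, does to their transcriptomes. Each line and siRNA was represented by 2 libraries. The libraries of PyMT-1099 LT held 27874077, 35005191, 29285403 and 35633505 reads (siCtl 1 and 2, then siNrf2 1 and 2). Those of Py2T LT held 29643136, 37070635, 30967721 and 35835938, and those of MT∆Ecad 30866728, 27088970, 31710626 and 34422018. The lines set the libraries apart: the first and second principal components, with 55.73% and 39.88% of the variance, separated the lines, and the next component held 1.95%.

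The targeted gene was lower in every siNrf2 library than in every siCtl library of its line. Nfe2l2, which encodes Nrf2 (Entrez 18024, GRCm38 chromosome 2, 75675513 to 75704663), fell from 113.1 ± 0.0534 to 29.51 ± 5.33 CPM in PyMT-1099 LT, from 86.65 ± 4.36 to 23.21 ± 1.86 in Py2T LT and from 208.1 ± 0.738 to 52.37 ± 2.27 in MT∆Ecad (mean ± SD, n = 2 libraries per group). The level left was 26.1%, 26.8% and 25.2% of that in siCtl. The log2 fold changes were −1.91, −1.86 and −1.97 (SE 0.118 each), with limma adjusted p of 0.000691, 0.000897 and 9.7e-05. On the 4 libraries of a line alone the Nfe2l2 adjusted p was 0.46 in PyMT-1099 LT, 1 in Py2T LT and 0.043 in MT∆Ecad. The difference between lines did not pass the test (limma adjusted p 0.997), and the log2 difference of MT∆Ecad from PyMT-1099 LT was −0.06 (95% interval −0.43 to 0.32) and from Py2T LT −0.11 (−0.49 to 0.26).

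**Figure D1:**
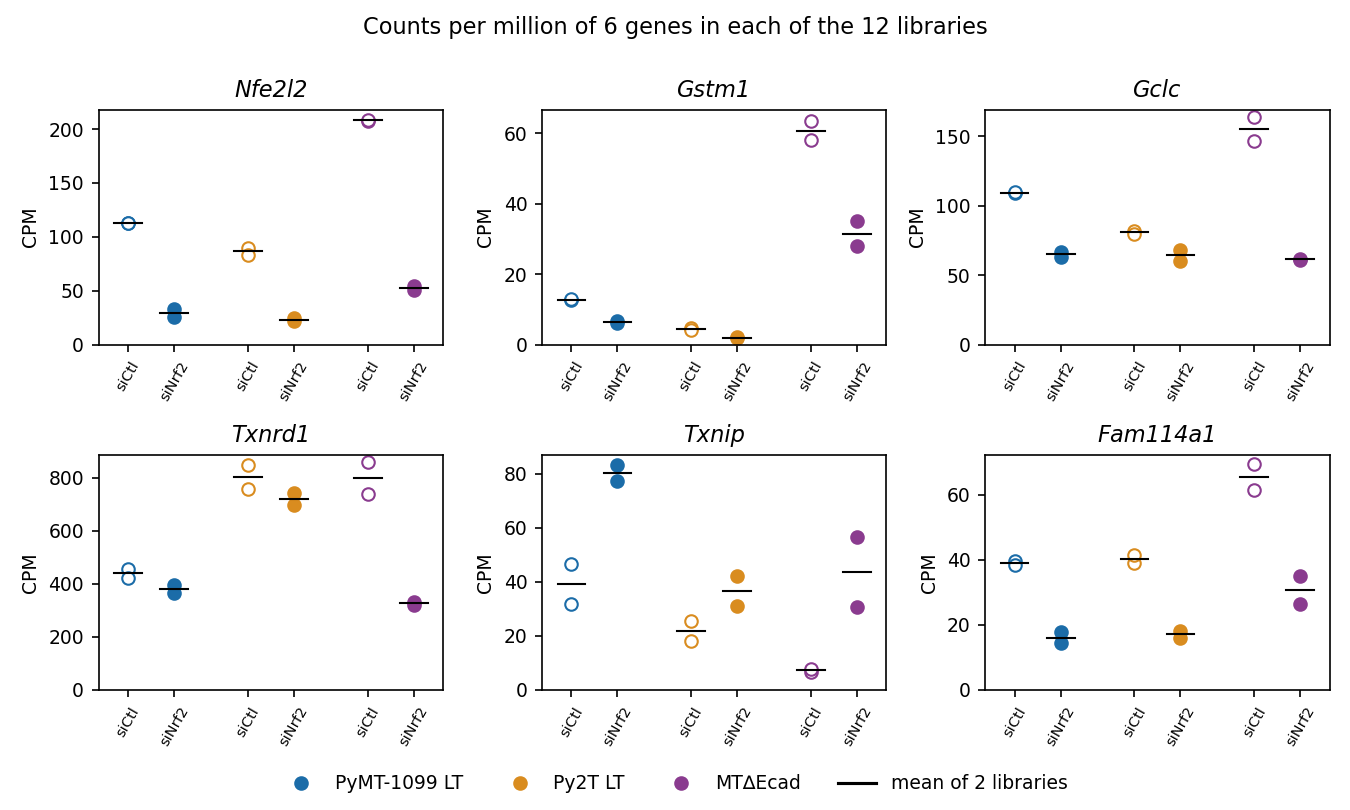
CPM (vertical axes, from 0) of 6 genes in each of the 12 libraries, with open circles for siCtl, filled circles for siNrf2 and a bar at the mean of the 2 libraries of a group. Nfe2l2 left 26.1%, 26.8% and 25.2% of its siCtl level in the 3 lines, while the fall of Txnrd1 and Gclc was deeper in MT∆Ecad than in Py2T LT.

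Averaged over the 3 lines, siNrf2 lowered NRF2 target genes. The largest falls with a known redox role were Gsta4, a glutathione S-transferase that conjugates products of lipid peroxidation (log2 fold change −1.71, SE 0.12), the quinone reductase Nqo1 (−1.21, SE 0.07) and Gstm1, another glutathione S-transferase (−0.91, SE 0.07). The other large falls were Tmem168 (−1.38), Fam114a1 (−1.17), Prkar2a, a regulatory subunit of protein kinase A (−0.95), the mitochondrial chaperonin Hspd1 (−0.95), the copine Cpne3 (−0.95) and Nxpe3 (−0.92). The 3′ UTRs of Tmem168, Fam114a1, Prkar2a and Cpne3 hold ACCATTT and those of Hspd1 and Nxpe3 hold GAGAAGT, whereas those of Gsta4, Nqo1 and Gstm1 hold neither. The largest rises were taken among genes that kept their sign in each line. Txnip, which binds and inhibits thioredoxin, led (1.38, SE 0.17), with C1qtnf1 (0.96), Tmem140 (0.92) and Parm1 (0.90, with ACCATTT). Next came the coagulation factor XIII subunit F13a1 (0.88), Fam214b (0.85) and Uba7, the activating enzyme for the ubiquitin-like Isg15 (0.82). Chac1, which degrades glutathione (0.78), the arrestin-like Arrdc4 (0.77) and the cytokine receptor chain Csf2rb (0.76) followed. All of these falls and rises passed limma's test on the average, with adjusted p from 0.00022 for Nqo1 to 0.024 for Chac1. The rises of Tmem140, Parm1, Uba7 and Csf2rb were 2.058, 2.131, 1.895 and 1.949 in MT∆Ecad. In Py2T LT they were 0.076, 0.07, 0.018 and 0.077, and in PyMT-1099 LT 0.614, 0.497, 0.562 and 0.242. C1qtnf1 had 2.135 in MT∆Ecad, 0.339 in PyMT-1099 LT and 0.414 in Py2T LT. By the F test the effect on these genes differed between lines (limma adjusted p at most 0.0495). No such difference passed for Txnip, F13a1, Fam214b, Chac1 or Arrdc4. Gsta4 and Gstm1 belong to families of similar genes between which the authors' counting could have split reads.

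Of the 40 NRF2 target genes on the fixed list, 38 were tested and 23 fell, 0 rose and 15 did not pass the test. Adjusted over the list alone, 25 fell. Besides Gsta4, Nqo1 and Gstm1, falls were found for both subunits of the enzyme that starts glutathione synthesis, Gclc (−0.79) and Gclm (−0.47, with ACCATTT), the S-formylglutathione hydrolase Esd (−0.85, with GAGAAGT), the cystine carrier Slc7a11 (−0.57), thioredoxin reductase Txnrd1 (−0.55), and the heme transporter Slc48a1 (−0.52). Also lower were the export pump Abcc1 (−0.46, with ACCATTT), sulfiredoxin Srxn1 (−0.44) and ferritin heavy chain Fth1 (−0.44, with ACCATTT). Smaller falls were found for Abcc4 (−0.39), Cbr3 (−0.30), Pgd (−0.29), Ephx1 (−0.29), Txn1 (−0.27), Ugdh (−0.27), Tkt (−0.26), G6pdx (−0.26), Cat (−0.25), Gsr (−0.20) and Prdx1 (−0.18, with ACCATTT). Of these, Gsr and Prdx1 lost their calls by edgeR and DESeq2 and kept them in 2 and 0 of 12 fits with a library left out. Cbr3 reversed to 0.03 by edgeR and 0.08 by DESeq2, and Pgd, Tkt and G6pdx lost their calls by edgeR. The heme oxygenase Hmox1, a commonly used NRF2 target, had a log2 fold change of −0.04 (SE 0.17, limma adjusted p 0.91). The list as a whole fell, with a median of −0.27 (camera adjusted p 6.7e-14, and adjusted p = 0.15 with an estimated correlation and 0.00057 by fry). Its median was −0.26 without the 5 members whose 3′ UTR holds either 7-mer. The blocked fit moved Ftl1 (−0.14, limma adjusted p 0.35 without the block and 0.0043 with it), Mgst1 (−0.30, 0.073 and 0.0033), Trim16 (−0.33, 0.079 and 0.0011) and Akr1b8 (0.10, 0.18 and 0.038) past the threshold. The remaining members, Osgin1 (0.11), Me1 (−0.04), Taldo1 (−0.07), Cbr1 (−0.06), Blvrb (−0.02), Pir (−0.12), Htatip2 (0.03), Ptgr1 (−0.05), Aox1 (−0.18) and Nampt (−0.16), passed it in neither fit.

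The pentose phosphate and NADPH genes also fell as a list, with 7 of 22 members lower and 0 higher, the same counts adjusted over the list alone, and a median of −0.10 (camera adjusted p 0.015, and adjusted p = 0.34 with an estimated correlation). Mthfd1 (−0.34), Pgd, Mthfd1l (−0.29) and Tkt had the largest of these falls, and the blocked fit called 9 lower and 2 higher. The 5 further redox lists did not pass camera on the average. Their counts of members that rose and fell, and then the same counts adjusted over the list alone, were 0 and 5 of 19, then 2 and 7, for the glutathione S-transferases (Gstp1 −0.57, Mgst2 −0.36, blocked fit 4 and 8), and 3 and 7 of 21, then 3 and 9, for thioredoxins, peroxiredoxins and superoxide enzymes (Prdx6 −0.38, blocked fit 4 and 10). They were 0 and 7 of 26, then 0 and 8, for carbonyl and quinone detoxification (Aldh3a1 −0.67 and Ugt1a6a −0.30, the latter with GAGAAGT, blocked fit 2 and 8), and 0 and 5 of 25, then 0 and 5, for heme and iron metabolism (Abcb6 −0.27 and Aco1 −0.24, the latter with ACCATTT, blocked fit 2 and 8). Glutathione synthesis and peroxidases had 2 and 4 of 18, then 3 and 4 (blocked fit 6 and 5), with a median of 0.04 and a mean of −0.03, which differ in sign.

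Proliferation genes fell on the average. Of 40 S-phase and replication genes, 26 fell and 0 rose (33 and 0 adjusted over the list alone). Their median was −0.31 (camera adjusted p 1.9e-16, and adjusted p = 0.15 with an estimated correlation). Among them were the DNA methylation factor Uhrf1 (−0.55, with ACCATTT), the replicative helicase subunit Mcm5 (−0.42) and the clamp loader subunit Rfc3 (−0.40). Of 41 mitosis genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone, 34 fell in the blocked fit). Their median was −0.23 (camera adjusted p 2.9e-09, and adjusted p = 0.15 with an estimated correlation). Members included Aurkb (−0.46), Cks1b (−0.32), Cenpa (−0.28) and Nek2 (−0.27). Of 30 MYC and ribosome biogenesis genes, 9 fell and 0 rose (17 and 0 adjusted over the list alone, 28 fell in the blocked fit). Their median was −0.27 (camera adjusted p 3.0e-09, and adjusted p = 0.30 with an estimated correlation). Nolc1 (−0.38, with ACCATTT), Odc1 (−0.37, with ACCATTT), Gar1 (−0.37) and Cad (−0.37) led this list. The fall of this list came from MT∆Ecad (median −0.62) and PyMT-1099 LT (−0.16), while Py2T LT showed none (−0.01, camera adjusted p 0.54). Cytosolic ribosomal proteins fell by a median of 0.06 (camera adjusted p 0.0052, and adjusted p = 0.64 with an estimated correlation), with 1 of 58 members called, Rps7 (−0.26), 0 adjusted over the list alone and 10 in the blocked fit. The list lost its call by DESeq2, and Rps7 by edgeR. Heat shock genes fell by a median of 0.10 (camera adjusted p 0.033, and adjusted p = 0.20 with an estimated correlation), with Hspd1 and Hsph1 (−0.36) the 2 members of 18 called, the same number adjusted over the list alone and 7 in the blocked fit. The heat shock list lost its call without the genes that hold either 7-mer (camera adjusted p 0.053), although its median stayed near (−0.085 against −0.100), and kept it in 8 of 12 fits with a library left out. In Py2T LT the medians of the ribosomal protein and heat shock lists were −0.005 and −0.017 (camera adjusted p 0.41 and 0.86).

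Interferon-stimulated genes, lysosome genes and stress-response genes rose on the average. The interferon-stimulated rise was carried by MT∆Ecad, with list medians of 0.88 there, 0.11 in PyMT-1099 LT and −0.07 in Py2T LT. Of 27 tested interferon-stimulated genes, 12 rose and 0 fell (17 and 1 adjusted over the list alone, 20 and 1 in the blocked fit). Their median was 0.27. Members included Xaf1 (0.60), Ifi27 (0.57), Trim30a (0.53) and Ddx58, the cytosolic RNA sensor RIG-I (0.48). This was the only list on the average to keep its call with an estimated correlation (camera adjusted p 2.3e-09, and adjusted p = 0.023 with an estimated correlation), and in the blocked fit it did not (adjusted p = 0.31 with an estimated correlation). In that fit, with its 3 residual degrees of freedom, no list in any contrast passed with an estimated correlation, so this loss is not particular to the list. Of 37 lysosome and autophagy genes, 15 rose and 0 fell (20 and 0 adjusted over the list alone, 23 and 4 in the blocked fit). Their median was 0.21 (camera adjusted p 1.3e-07, and adjusted p = 0.30 with an estimated correlation). The proton pump subunit Atp6v0d1 (0.71), the sialidase Neu1 (0.61) and Gabarap (0.43) were among those that rose. The integrated stress response list had 6 members higher and 1 lower of 28 (12 and 1 adjusted over the list alone, 15 and 1 in the blocked fit). Their median was 0.21 (camera adjusted p 0.00025, and adjusted p = 0.46 with an estimated correlation). Chac1, Sesn2 (0.49) and Ddit4 (0.47) rose, and Slc7a11, which is also an NRF2 target, fell. ER chaperones and unfolded protein response genes had 3 higher and 1 lower of 21, the same adjusted over the list alone and 9 and 1 in the blocked fit, with a median of 0.11 (camera adjusted p 0.015, and adjusted p = 0.34 with an estimated correlation). Dnajb9 (0.30, with GAGAAGT), Sel1l (0.24) and Edem1 (0.20) rose and Manf (−0.45, with ACCATTT) fell.

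Matrix and mesenchymal genes rose as lists on the average, carried by MT∆Ecad (medians 0.32 and 0.29). In Py2T LT the matrix list had a median of −0.08 (camera adjusted p 0.033, and adjusted p = 0.48 with an estimated correlation) and the mesenchymal list one of −0.06. Of 44 extracellular matrix and cross-linking genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone, 19 and 3 in the blocked fit). Their median was 0.08 (camera adjusted p 0.00056, and adjusted p = 0.18 with an estimated correlation). Col6a2 (0.86), Col6a1 (0.62) and Col5a1 (0.40) rose and Timp3 (−0.48, with both 7-mers) fell. Of 38 mesenchymal and EMT genes, 7 rose and 2 fell (the same adjusted over the list alone, 17 and 4 in the blocked fit). Their median was 0.08 (camera adjusted p 0.0029, and adjusted p = 0.34 with an estimated correlation). Members included Itgb3 (0.67), Mmp2 (0.57) and Tead2 (−0.45). TGF-beta target genes had 5 higher and 0 lower of 26 (the same adjusted over the list alone, 10 and 1 in the blocked fit). Their median was 0.12 (camera adjusted p 0.0044, and adjusted p = 0.34 with an estimated correlation). Members included Tgfbi (0.37), Bhlhe40 (0.36), Tgfbr2 (0.34, with GAGAAGT) and Pmepa1 (0.30) as the largest. Tgfbi, Bhlhe40 and Pmepa1 lost their calls by edgeR and without a filter, Tgfbi also by DESeq2, and each kept it in 2 of 12 fits with a library left out. The TGF-beta and fibroblast lists had medians of −0.005 and −0.004 in Py2T LT (camera adjusted p 0.86 and 0.81). Fibroblast markers had 2 of 5 higher (3 adjusted over the list alone), Gsn (0.49) and Pdgfra (0.27), with a median of 0.27 (camera adjusted p 0.0069, and adjusted p = 0.30 with an estimated correlation). Epithelial genes rose on the average but not in MT∆Ecad (median 0.007, camera adjusted p 0.98), with medians of 0.06 in PyMT-1099 LT and 0.13 in Py2T LT. On the average 3 were higher and 1 lower of 38 (the same adjusted over the list alone, 10 and 4 in the blocked fit). Their median was 0.11 (camera adjusted p 0.033, and adjusted p = 0.18 with an estimated correlation). Spint2 (0.43), Krt18 (0.32) and F11r (0.23, with ACCATTT) were higher and Ppl (−0.49) lower. This list lost its call by edgeR, by DESeq2 and with a filter at CPM 5, and kept it in 8 of 12 fits with a library left out. Without the 11 members that hold either 7-mer the call was lost too (camera adjusted p 0.36), with the median unchanged (0.111 against 0.112).

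**Figure D2:**
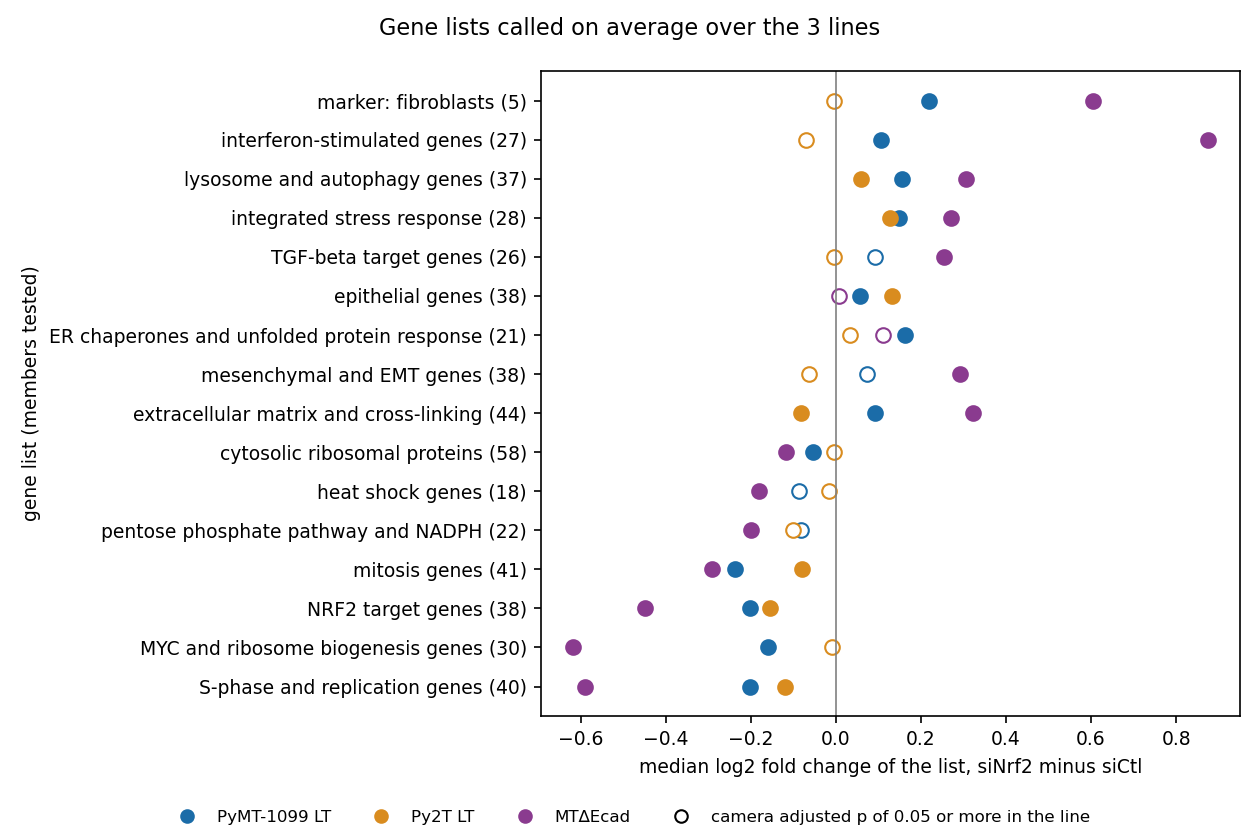
Median log2 fold change (siNrf2 minus siCtl, horizontal axis) in each line of the 16 gene lists that camera called on the average, with the number of tested members in brackets and open circles where camera's adjusted p in the line was 0.05 or more. In MT∆Ecad the medians ran from −0.62 for MYC and ribosome biogenesis genes to 0.88 for interferon-stimulated genes.

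Lists that did not pass camera on the average held single called members. Fatty acid synthesis and oxidation had 6 higher and 1 lower of 29 (8 and 1 adjusted over the list alone), with Acss2 (0.38, with ACCATTT), Ech1 (0.37) and Cpt1a (0.36). The list passed only in the blocked fit (11 higher and 5 lower, camera adjusted p 0.060 without the block and 0.041 with it, and in the blocked fit adjusted p = 0.36 with an estimated correlation). The counts that follow give members that rose and fell, then the same counts adjusted over the list alone, then those of the blocked fit. They were 3 and 1 of 32, then 7 and 2, then 11 and 5, for hypoxia and glycolysis (Slc16a1 −0.40, Pdk1 0.28, Hk2 0.23, P4ha1 0.19). They were 2 and 2 of 11, then 3 and 3, then 5 and 5, for ABC efflux transporters (Abcg1 0.44, Abcc3 0.23), and 3 and 1 of 26, then 3 and 3, then 7 and 5, for ferroptosis regulators (Aifm2 0.32, Lpcat3 0.29). They were 2 and 3 of 27, then 4 and 3, then 8 and 6, for NF-kB and inflammatory genes (Il33 0.38 with either 7-mer, Cxcl5 −0.31, Vcam1 0.25, and Tnfaip2 −0.25 with ACCATTT). They were 1 and 2 of 22, then 1 and 2, then 3 and 8, for p53 targets (Perp −0.61, Btg2 0.47, and Phlda3 −0.35, Perp and Phlda3 with ACCATTT), and 1 and 2 of 24, then 1 and 2, then 2 and 2, for cholesterol synthesis (Tm7sf2 0.35, and Insig1 −0.24 with both 7-mers). YAP/TEAD targets had 1 and 2 of 26, then 1 and 2, then 4 and 6 (Lats2 0.24, Ajuba −0.24, and Wwtr1 −0.23 with both 7-mers), with a median of −0.02 and a mean of 0.00. Metallothioneins and zinc transport had 2 and 1 of 8, then 2 and 2, then 2 and 3 (Mt2 0.52, Mt1 0.35, Slc39a6 −0.26). Immediate early genes had 2 and 1 of 26, then 0 and 0, then 9 and 4 (Btg2 and Ier5, −0.29), and the NRF family and KEAP1 regulators 0 and 2 of 12, then 0 and 2, then 2 and 3 (Gsk3b −0.32, with both 7-mers, and Mafg −0.29, with GAGAAGT). Proteasome subunits had 0 and 1 of 33, then 0 and 1, then 1 and 7 (Psma7 −0.27, with GAGAAGT), and nuclear genes of oxidative phosphorylation 0 and 1 of 75, then 0 and 0, then 8 and 4 (Ndufab1 −0.31). Among the markers of other cell types, immune cells had 1 and 0 of 5, then 1 and 0, then 1 and 0 (Csf1r 0.64). Endothelial cells had 0 and 0 of 3, then 1 and 0, then 1 and 0. Luminal mammary cells had 2 and 0 of 8, then 2 and 0, then 3 and 1 (Krt18, and Esr1 0.24 with either 7-mer), and basal mammary cells 2 and 1 of 6, then 2 and 1, then 2 and 2 (Krt14 −0.88, Trp63 0.59, Mylk 0.35). Trp63 reversed to −0.08 by edgeR and lost its call by DESeq2 (0.19), and Mylk lost its call by both and with a pseudocount of 0.25.

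In total 1532 of 12502 genes were called on the average by limma, 749 higher and 783 lower, and 1 of the higher and 5 of the lower changed at least 2-fold. The blocked fit called 4997 (2370 higher, 2627 lower) and edgeR 856. Leaving out a single library gave 660 without MT∆Ecad siCtl 1, 680 without MT∆Ecad siNrf2 2, 697 and 804 without Py2T LT siCtl 2 or 1, and 774, 803, 932 and 925 without PyMT-1099 LT siCtl 1, siCtl 2, siNrf2 1 or siNrf2 2. Of the further named genes called on the average, Abcg1, Cxcl5, Esr1, Ier5, Il33, Insig1, Mmp2, Ndufab1, Trim30a and Vcam1 lost their calls by both edgeR and DESeq2. Abcb6, Ajuba, Cenpa, Ddit4, F11r, Hk2, Lpcat3, Mgst2, Pdk1 and Tm7sf2 lost them by edgeR alone of these tools. With a library left out Hk2, Ier5 and Vcam1 kept theirs in 1 of 12 fits and Abcc3, Ddit4, F11r, Il33, Insig1 and Tm7sf2 in 2.

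In PyMT-1099 LT, NRF2 target genes fell as a list with a median of −0.20 (camera adjusted p 1.7e-09, and adjusted p = 0.20 with an estimated correlation and 0.057 by fry). The largest single-gene rises were the small proline-rich proteins of the cornified envelope Sprr2g (log2 fold change 1.28, from 5.59 ± 1.5 to 14.9 ± 3.0 CPM, mean ± SD, n = 2) and Sprr1b (1.09), the collagen VI chain Col6a2 (1.19, from 25.3 ± 1.9 to 59.1 ± 2.8 CPM), the transcription factor Arid3a (1.04) and Clrn3 (1.01). The largest falls after Nfe2l2 were Tmem168 (−1.67, with ACCATTT), Nqo1 (−1.35, from 3.06 ± 0.16 to 0.588 ± 0.038 CPM), Fam114a1 (−1.24, with ACCATTT) and Perp, a desmosomal p53 target (−1.02, with ACCATTT), with limma adjusted p between 0.0043 for Clrn3 and 0.024 for Sprr1b. Sprr2g, Sprr1b, Arid3a and Clrn3 lost their calls by edgeR, and on the 4 libraries of the line all named rises and falls lost them. With a library left out Sprr1b and Arid3a kept theirs in 5 and 7 of 12 fits and the other named genes in 9 to 12. Of the NRF2 targets, 3 fell over all genes, Nqo1, Gclc (−0.74) and Gstm1 (−0.92), and 7 adjusted over the list alone (13 in the blocked fit).

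Camera called 13 lists in this line. Besides the NRF2 targets, S-phase (median −0.20), mitosis (−0.24), MYC and ribosome biogenesis (−0.16), p53 target (−0.11) and ribosomal protein genes (−0.05) fell. Lysosome (0.16), integrated stress response (0.15), ER chaperone (0.16), interferon-stimulated (0.11), extracellular matrix (0.09), epithelial genes (0.06) and fibroblast markers (0.22) rose. Without the genes that hold either 7-mer the p53, epithelial, matrix and fibroblast lists lost their calls (camera adjusted p 0.67, 0.93, 0.051 and 0.052). The p53 median was then −0.05, without 12 of 22 members, and the epithelial median 0.00, while the matrix (0.11) and fibroblast (0.22) medians kept their size. The epithelial call was also lost by DESeq2, with a pseudocount of 0.25, without a filter and with a filter at CPM 5, the fibroblast call without a filter and the ribosomal protein call by DESeq2. With an estimated correlation 0 lists were called, with adjusted p of 0.20 for the NRF2 targets, mitosis, p53, interferon and epithelial lists, 0.29 for ER chaperones, 0.33 for S-phase, lysosome and matrix genes, 0.44 for fibroblast markers, 0.56 for the stress response and MYC lists and 0.77 for ribosomal proteins. Among these lists only Gclc, Nqo1 and Gstm1, Perp and Col6a2 were called as single genes over all genes tested. In the blocked fit 12 S-phase, 9 mitosis and 5 MYC and ribosome biogenesis genes fell and 0 rose. Lysosome genes had 11 higher and 1 lower in that fit, matrix genes 9 and 4 and stress response genes 8 and 1. The blocked fit added TGF-beta targets (median 0.09, camera adjusted p 0.029) and oxidative phosphorylation genes (0.04, 0.046), with adjusted p of 0.45 and 0.69 with an estimated correlation.

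The line had 65 called genes, 42 higher and 23 lower, and 1125 (631 higher, 494 lower) in the blocked fit, 13 by edgeR, and 0 by limma on its own 4 libraries, where 1202 genes had an unadjusted p under 0.05. Without siNrf2 1 of this line 7 genes were called, and 19, 17 and 31 without its siCtl 1, siCtl 2 or siNrf2 2. The count was 34 without any of the 4 libraries of MT∆Ecad in turn and 41 and 40 without Py2T LT siCtl 1 or 2.

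In Py2T LT, few genes passed the test. Gsta4 fell most (−2.16, from 13.6 ± 4.9 to 2.16 ± 0.14 CPM, mean ± SD, n = 2), followed by Nfe2l2, Fam114a1 (−1.19, with ACCATTT), the zinc finger gene Zfp365 (−1.18, with GAGAAGT) and Medag, a gene of adipocyte differentiation (−1.09). Of 7 called rises the naming rule took Hsd11b1, which regenerates active glucocorticoid (0.97, from 3.19 ± 0.22 to 7.27 ± 1.6 CPM), the serotonin transporter Slc6a4 (0.77) and the hyaluronan synthase Has3 (0.76), with limma adjusted p from 0.0087 for Gsta4 and Medag to 0.046 for Has3. Most of these calls were fragile. With a library left out Hsd11b1, Slc6a4 and Has3 kept them in 1, 5 and 0 of 12 fits, Zfp365 and Fam114a1 in 2 and 4, and Gsta4 and Medag in 10 each. The 3 named rises lost theirs by edgeR, Slc6a4 and Has3 also by DESeq2, and the named rises and Zfp365 with a pseudocount of 0.25, and on the 4 libraries of the line all named genes lost them. Of the NRF2 targets 3 fell, Gsta4, Gstm1 (−0.88) and the epoxide hydrolase Ephx1 (−0.74), and 5 adjusted over the list alone (5 in the blocked fit), with a list median of −0.16 (camera adjusted p 1.6e-08, and adjusted p = 0.41 with an estimated correlation and 0.085 by fry). Nqo1 was −0.37 (limma adjusted p 0.65).

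Glutathione S-transferases fell in this line, with 2 of 19 members called and 3 adjusted over the list alone (4 in the blocked fit, median −0.14, camera adjusted p 2.8e-06, and adjusted p = 0.49 with an estimated correlation). Epithelial genes rose, with a median of 0.13 and 0 of 38 members called either way. They kept the call with an estimated correlation (camera adjusted p 2.8e-06, and adjusted p = 0.034 with an estimated correlation). In the blocked fit they did not (adjusted p = 0.37 with an estimated correlation), and neither did any other list. Camera also called falls of carbonyl and quinone detoxification (median −0.13), S-phase (−0.12), mitosis (−0.08), cholesterol synthesis (−0.09) and extracellular matrix genes (−0.08), and rises of integrated stress response (0.13) and lysosome genes (0.06). With an estimated correlation their adjusted p values were 0.41, 0.54, 0.56, 0.61, 0.48, 0.54 and 0.54 in that order. The call of the mitosis list was also lost by edgeR, DESeq2, TMM and median-of-ratios scaling, and that of the matrix list with a pseudocount of 5 and a filter at CPM 5. Without the genes that hold either 7-mer the matrix and cholesterol synthesis lists lost theirs (camera adjusted p 0.079 and 0.15), with medians of −0.056 against −0.081 and −0.072 against −0.089. The blocked fit added falls of YAP/TEAD target genes (median −0.11, camera adjusted p 0.0085) and of pentose phosphate and NADPH genes (−0.10, 0.030), and a rise of luminal markers (0.06, 0.021), each with adjusted p = 0.42 with an estimated correlation.

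The line had 19 called genes, 7 higher and 12 lower, against 674 at an unadjusted p under 0.05. The blocked fit called 127 (43 higher, 84 lower), edgeR 6, DESeq2 33 and limma on the line's own 4 libraries 0, where 405 genes had an unadjusted p under 0.05. With median-of-ratios scaling 7 rose and 7 fell, and leaving out any single library of the 12 gave between 5 (without Py2T LT siCtl 2, for example) and 11.

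In MT∆Ecad the response was broad. Cd93, a C-type lectin-like receptor, rose most (log2 fold change 2.48, from 12.3 ± 3.9 to 73.3 ± 20 CPM, mean ± SD, n = 2), with Txnip (2.38), the small leucine-rich proteoglycan Ogn (2.16, from 21.4 ± 0.37 to 99.2 ± 1.4 CPM, with ACCATTT), C1qtnf1 (2.13) and Parm1 (2.13, with ACCATTT). After Nfe2l2, the largest falls were Nqo1 (−1.90, from 5.03 ± 0.22 to 0.617 ± 0.11 CPM), Gsta4 (−1.85, from 258.5 ± 25 to 71.1 ± 7.7 CPM), the kallikrein-related peptidase Klk10 (−1.83) and Tafa5 (−1.65), with limma adjusted p between 5.7e-06 for Ogn and 0.0065 for Tafa5. On the 4 libraries of the line Txnip, C1qtnf1 and Tafa5 lost their calls. Of the 38 tested NRF2 targets 23 fell, and 24 adjusted over the list alone. Their median was −0.45 (camera adjusted p 3.9e-11, and adjusted p = 0.17 with an estimated correlation and 0.00044 by fry). Esd (−1.36), Gclc (−1.32), Txnrd1 (−1.28), Srxn1 (−1.06), Gclm (−1.04) and Cbr3 (−1.01) fell by at least 2-fold here. Glutathione S-transferases had 3 members higher and 6 lower of 19 (4 and 6 adjusted over the list alone, 6 and 7 in the blocked fit) and did not pass camera, with a median of 0.10 and a mean of −0.23 of opposite sign. Thioredoxins, peroxiredoxins and superoxide enzymes had 3 higher and 7 lower of 21 (4 and 10 adjusted over the list alone, 5 and 11 in the blocked fit).

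Replication and ribosome biogenesis genes fell in MT∆Ecad. Of 40 S-phase genes 27 fell and 0 rose (35 and 0 adjusted over the list alone). Their median was −0.59 (camera adjusted p 2.4e-19, and adjusted p = 0.14 with an estimated correlation). Members included Uhrf1 (−0.89) and Mcm5 (−0.85). Of 30 MYC and ribosome biogenesis genes 20 fell and 0 rose (23 and 0 adjusted over the list alone). Their median was −0.62 (camera adjusted p 1.0e-12, and adjusted p = 0.23 with an estimated correlation). Members included Odc1, the rate-limiting enzyme of polyamine synthesis (−0.95), Nolc1 (−0.84) and Cad, which starts pyrimidine synthesis (−0.75). Mitosis genes had 11 of 41 lower (15 adjusted over the list alone, 27 in the blocked fit). Their median was −0.29 (camera adjusted p 8.3e-08, and adjusted p = 0.17 with an estimated correlation). Pentose phosphate and NADPH (median −0.20), heat shock (−0.18), proteasome (−0.14) and ribosomal protein genes (−0.12) fell as lists too, with adjusted p of 0.42, 0.19, 0.54 and 0.71 with an estimated correlation. The blocked fit called 17 ribosomal protein genes lower against 5, and 13 proteasome genes lower against 1. By edgeR and DESeq2 the calls of the pentose phosphate and proteasome lists were lost.

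Interferon-stimulated genes formed the strongest rise in MT∆Ecad. Of 27 members 19 rose and 0 fell (22 and 0 adjusted over the list alone). Their median was 0.88, and the call held with an estimated correlation (camera adjusted p 2.3e-13, and adjusted p = 0.0082 with an estimated correlation). It did not hold when that was combined with the block (adjusted p = 0.25 with an estimated correlation), where no list passed. Trim30a (1.49), Xaf1 (1.24), Ifi27 (1.12) and Ddx58 (1.07) rose, as did, among members chosen after their values were seen, the transcription factor Irf7 (1.69), Gbp2 (1.27), Isg15 (1.25) and the immunoproteasome subunit Psmb9 (0.89). Of 44 extracellular matrix genes 17 rose and 1 fell (19 and 1 adjusted over the list alone, 29 and 2 in the blocked fit). Their median was 0.32 (camera adjusted p 6.0e-08, and adjusted p = 0.086 with an estimated correlation). Members included Col6a2 (1.46), Col6a1 (1.11) and Col5a1 (1.04) and, chosen after their values were seen, Col1a1 (1.49) and Thbs2 (1.11). Of 38 mesenchymal and EMT genes 14 rose and 2 fell (16 and 2 adjusted over the list alone, 21 and 4 in the blocked fit). Their median was 0.29 (camera adjusted p 2.1e-05, and adjusted p = 0.23 with an estimated correlation). Members included Postn (2.00, chosen after its values were seen), the gelatinase Mmp2 (1.74) and the integrin chain Itgb3 (1.40). Fibroblast markers had 4 of 5 higher, the same adjusted over the list alone, including Gsn (0.89) and Pdgfra (0.60), with a median of 0.60 (camera adjusted p 0.0012, and adjusted p = 0.23 with an estimated correlation). Lysosome genes had 15 higher and 1 lower of 37 (19 and 1 adjusted over the list alone, 22 and 3 in the blocked fit) with a median of 0.31, led by Atp6v0d1 (1.09). Fatty acid genes had 8 and 1 of 29 (12 and 2 adjusted over the list alone, 16 and 4 in the blocked fit) with 0.27. TGF-beta targets had 7 and 0 of 26 (8 and 0 adjusted over the list alone, 13 and 2 in the blocked fit) with 0.26, including Tgfbi (1.47). Integrated stress response genes had 4 and 0 of 28 (the same adjusted over the list alone, 13 and 3 in the blocked fit) with 0.27. These 4 lists passed camera, and with an estimated correlation their adjusted p values were 0.42, 0.54, 0.36 and 0.71 in that order. The stress response list lost its call without the genes that hold either 7-mer (camera adjusted p 0.060), with its median unchanged at 0.271. Krt14 (−1.42, from 132 ± 14 to 48.8 ± 1.9 CPM) fell and Trp63 (1.77) and Mylk (0.86), other basal markers, rose.

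The line had 2164 called genes, 1111 higher and 1053 lower, of which 177 and 57 changed at least 2-fold. The blocked fit called 5324 (2676 higher, 2648 lower), limma on the line's own 4 libraries called 1116, and the count was 576, 1339, 1364 and 625 without its siCtl 1, siCtl 2, siNrf2 1 or siNrf2 2.

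The lines differed in how far and in which genes they responded. By the F test, 273 genes responded differently between lines, and by pairs 226 did between MT∆Ecad and PyMT-1099 LT, 437 between MT∆Ecad and Py2T LT and 1 between Py2T LT and PyMT-1099 LT. In the blocked fit the counts by pairs were 1810, 2859 and 7 in the same order. The smallest p-values belonged to Ogn, the membrane metalloendopeptidase Mme, Csf2rb, the costimulatory receptor Cd28 and Fam135b, which rose in MT∆Ecad by 2.16, 1.95, 1.95, 1.82 and 1.33 (limma adjusted p of the difference 0.00013, 0.00086, 0.0015, 0.0029 and 0.0052). In the PyMT lines Ogn had no reads and Mme, Cd28 and Fam135b lay at means of at most 0.115 CPM, near the limit of 0.1107 that a count of 0 allows, so their response there was not measurable. By edgeR the between-line calls of all 5 genes were lost, and by DESeq2 those of Ogn, Mme, Cd28 and Fam135b. The 3′ UTRs of Ogn, Mme, Cd28 and Fam135b hold ACCATTT, although these genes rose. Several NRF2 targets also responded unequally: Nqo1 fell by 1.90 in MT∆Ecad and had −0.37 in Py2T LT (limma adjusted p of the difference 0.0096), and Txnrd1 (−1.28 and −0.16, 0.0093), Gclc (−1.32 and −0.32, 0.014) and Gclm (−1.04 and −0.15, 0.017) did likewise, whereas Gstm1, Fam114a1 and Nfe2l2 each gave a limma adjusted p of the difference of 0.997.

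The count of 273 was 2377 in the blocked fit, 20 by edgeR, and between 29 (without MT∆Ecad siCtl 1) and 189 with a single library left out. It was 60 without MT∆Ecad siNrf2 2, 117 without MT∆Ecad siCtl 2, 174 without MT∆Ecad siNrf2 1, 138, 105 and 178 without Py2T LT siCtl 1, siCtl 2 or siNrf2 2, and 124, 124, 123 and 144 without PyMT-1099 LT siCtl 1, siCtl 2, siNrf2 1 or siNrf2 2.

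**Figure D3:**
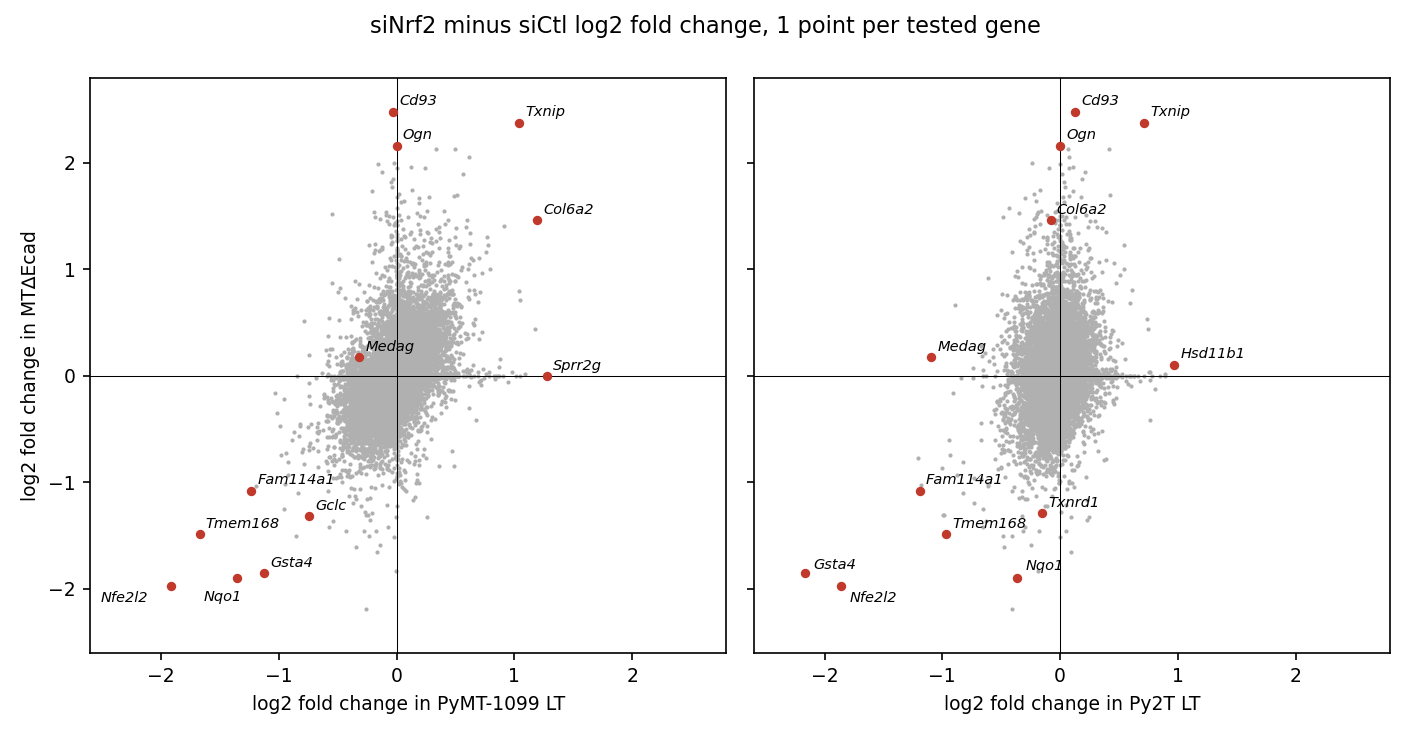
Log2 fold change (siNrf2 minus siCtl) in MT∆Ecad on the vertical axes against PyMT-1099 LT (left) and Py2T LT (right), with 1 grey point per tested gene and named genes in red. Nfe2l2 lies near −1.9 in each line, while Cd93 (2.48) and Ogn (2.16) stand high in MT∆Ecad alone among the lines shown.

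The lines shared falling genes. The falls called in PyMT-1099 LT and Py2T LT had 4 genes in common against 0.02 for independent lists of these sizes, those of PyMT-1099 LT and MT∆Ecad 15 against 1.94, and those of Py2T LT and MT∆Ecad 9 against 1.01. The 4 genes called lower in every line were Nfe2l2, Gstm1, Fam114a1 and, outside the naming rule and chosen after its values were seen, the mitochondrial adenylate kinase Ak3 (−0.50, −0.59 and −0.43 in PyMT-1099 LT, in Py2T LT and in MT∆Ecad). No gene was called higher in every line. Rises shared by PyMT-1099 LT and MT∆Ecad numbered 5 against 3.73, among them Col6a2 and Arid3a. In the blocked fit 37 genes fell and 10 rose in every line, among them Gsta4, Gstp1, Krt14, Fth1, Esd and Tmem168 as falls and Atp6v0d1, Neu1, Mt2 and Csf1r as rises. Of the 1053 genes called lower in MT∆Ecad, 83.6% also had a negative log2 fold change in PyMT-1099 LT and 82.5% in Py2T LT, where 50.2% and 57.5% of all tested genes did. Of the 1111 called higher, 75.8% and 53.3% had a positive one, against 47% and 40.9% of all tested genes. Across the 12502 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.469 between PyMT-1099 LT and MT∆Ecad (Spearman's rho 0.504), 0.372 between PyMT-1099 LT and Py2T LT (0.360) and 0.222 between Py2T LT and MT∆Ecad (0.228). The second of these was −0.10 without Py2T LT siNrf2 1 and 0.064 without Py2T LT siCtl 2, and the last was 0.036 without Py2T LT siNrf2 1 and 0.14 without Py2T LT siCtl 2. Either library left out makes a Py2T LT pair incomplete, so the effect of the replicate number enters the log2 fold changes of that line.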

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

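The tests of a stronger knockdown and of a rise of the same size in every line were chosen after the results were seen, and the other tests were written before them. The results listed first were singled out because the siNrf2 effect differed between lines in limma's F test (adjusted p from 0.00013 for Ogn to 0.050 for C1qtnf1), and the values are differences of log2 fold changes. MT∆Ecad minus PyMT-1099 LT was 2.51 for Cd93, 2.16 for Ogn, 1.86 for Cd28, 1.81 for Trp63, 1.80 for C1qtnf1, 1.52 for Trim30a, 1.14 for Acss2, 0.90 for Vcam1 and −1.83 for Klk10. MT∆Ecad minus Py2T LT was 2.06 for Parm1, 2.05 for Mme, 1.98 for Tmem140, 1.92 for Mmp2, 1.88 for Uba7, 1.87 for Csf2rb, 1.69 for Tgfbi, 1.54 for Col6a2, 1.36 for Fam135b, 1.30 for Xaf1, 1.27 for Medag, 1.09 for Col5a1, 1.06 for Ddx58, 0.997 for Mylk, 0.77 for Esr1 and 0.73 for Ephx1. On the negative side it was −1.53 for Nqo1, −1.18 for Odc1, −1.13 for Txnrd1, −1.08 for Cbr3, −0.995 for Gclc, −0.89 for Gclm, −0.80 for Has3, −0.73 for Slc6a4 and −0.72 for Abcc1. Py2T LT minus PyMT-1099 LT was −1.28 for Sprr2g and −1.03 for Clrn3. In 1 of the 2 lines compared, the group means of Ogn, Cd28, Trp63, Klk10, Mme, Fam135b, Slc6a4, Sprr2g and Clrn3 were at most 0.115 CPM, near the limit of a count of 0, so their differences show where they are expressed and not that measurable responses differed. Those of Trim30a, Vcam1, Parm1, Mmp2, Uba7, Csf2rb, Col6a2, Cbr3, Mylk and Has3 stayed below 1 CPM in 1 line, where log2(CPM + 1) understates a change.

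Gene lists were singled out in the same way, where camera called the difference between lines, which it did in 38 of 114 tests, and in 2 with an estimated correlation. The median difference of MT∆Ecad from Py2T LT was 0.93 for interferon-stimulated genes, 0.71 for fibroblast markers, 0.39 for mesenchymal and EMT genes, 0.38 for extracellular matrix genes, 0.36 for TGF-beta targets, 0.23 for fatty acid genes, 0.21 for lysosome genes and 0.20 for cholesterol synthesis. It was −0.61 for MYC and ribosome biogenesis, −0.51 for S-phase genes, −0.25 for NRF2 targets, −0.24 for mitosis genes, −0.18 for heat shock genes, −0.14 for ribosomal proteins, −0.12 for proteasome subunits and −0.12 for epithelial genes. The median difference of MT∆Ecad from PyMT-1099 LT was 0.68 for interferon-stimulated genes, 0.48 for fibroblast markers, 0.27 for mesenchymal and EMT genes, 0.23 for extracellular matrix genes, 0.22 for TGF-beta targets and 0.16 for fatty acid genes. It was −0.45 for MYC and ribosome biogenesis, −0.38 for S-phase genes, −0.28 for NRF2 targets, −0.11 for mitosis genes and −0.077 for proteasome subunits. For Py2T LT minus PyMT-1099 LT the medians were −0.27 for interferon-stimulated genes, −0.22 for fibroblast markers, −0.18 for extracellular matrix genes, −0.15 for glutathione S-transferases, −0.12 for ER chaperones and −0.12 for lysosome genes, and 0.14 for p53 targets, mitosis genes and MYC and ribosome biogenesis, 0.075 for S-phase genes and 0.05 for ribosomal proteins. The 2 tests called with an estimated correlation were the interferon-stimulated genes of MT∆Ecad against each other line (adjusted p 0.0106 each).

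The 668 genes outside the redox lists that were called lower on the average with a negative log2 fold change in each line, called there or not, may in part be silenced directly by the siRNA through short matches in their 3′ UTRs. The top 5 7-mers chosen in a single line had a mean z of −5.54 in the lines held out. The bound set beforehand, taken on the mean over the 2 held-out lines, was met for each line, with −4.04 for those chosen in MT∆Ecad. In Py2T LT alone the latter had only −2.27, short of that bound, and TTTTTAA (−0.10) and TTTTTTA (0.30) did not recur there. ACCATTT ranked first in each line (z −12.05, −11.41 and −8.02 in PyMT-1099 LT, in Py2T LT and in MT∆Ecad), and both it and GAGAAGT occur in the Nfe2l2 mRNA (2 of 2, where 13.9% of the tested 7-mers do), which an siRNA against it would require, but the siRNA sequences are not in the labels. Of 639 such genes with a 3′ UTR 36.8% hold either 7-mer, against 22.1% of 11100 other genes, an excess that is no separate test, since the 7-mers were chosen by their tie to falling genes. Most hold neither and are not explained by these 7-mers, and taking out a gene length trend left the median at −0.295 against −0.302.

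More genes were called in MT∆Ecad than in the other lines, and depth does not account for it. With all libraries thinned to the smallest total at least 2067 genes were called in MT∆Ecad, against 50 to 58 and 13 to 17. A stronger knockdown was not found, since the larger difference in the Nfe2l2 fold change was −0.68 standard errors. The 95% intervals of the log2 differences reached −0.43 and −0.49, so a somewhat deeper fall stays possible. Nfe2l2 also started higher in siCtl of MT∆Ecad (208.1 CPM, against 113.1 in PyMT-1099 LT and 86.65 in Py2T LT), and only RNA was measured. Higher NRF2 activity before the knockdown could contribute, since the NRF2 targets were higher in siCtl of MT∆Ecad than of PyMT-1099 LT (camera p 0.015, median 0.302) and of Py2T LT (1.5e-05, median 0.643). With an estimated correlation these p-values were 0.31 and 0.099. MT∆Ecad also comes from another tumour model than the other lines. Its name marks E-cadherin, which Cdh1 encodes, with ∆, and its siCtl libraries held little Cdh1 (0.3929 CPM, against 49.68 in PyMT-1099 LT and 13.88 in Py2T LT). With a single line of this kind these differences cannot be separated from the line.

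The rise of interferon-stimulated genes in MT∆Ecad is unlikely to come from immune cells in the cultures, because Ptprc, Tyrobp and Fcer1g reached at most 0.087 CPM in its siNrf2 libraries. A rise of the same size in every line would not give list medians of 0.88 here, 0.11 in PyMT-1099 LT and −0.07 in Py2T LT, but the adjusted p of this difference (0.0106 with an estimated correlation) is the value that singled the list out and no separate evidence. A response to the siNrf2 reagent that only this line can mount and a response to the loss of Nrf2 remain possible and could not be told apart, since no other siNrf2 reagent was used.

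By the count fixed beforehand, over splits that keep or part the replicate pairs, chance cannot be excluded for the number of genes called on the average: 5 of 100 splits, the real one included, reached at least its 1532 genes, and the highest other reached 4261. The 4 larger splits divide Py2T LT by replicate number and MT∆Ecad by siRNA, and PyMT-1099 LT by replicate number (4261 and 3804) or by siRNA (3409 and 1845), which points to a structure of the samples that follows the replicate number. These 4 part only 2 or 4 of the 6 pairs. They also keep the siRNA division of MT∆Ecad and so still hold its siNrf2 effect, which limits what the count over all splits says about chance. Among the 32 splits that part all 6, as the real one does, it was the highest, which goes against chance. The highest other had 643 genes, and in the blocked fit the real split had 4997 and the highest other 3934. That other split divides PyMT-1099 LT and MT∆Ecad by siRNA and still holds siNrf2 effects, so its counts do not measure chance alone. Each of the 32 that called any gene divides MT∆Ecad by siRNA. Those that do not called no gene in either fit, but there the siNrf2 effect of MT∆Ecad lies within the groups.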

How the results depend on the processing

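The removal of genes whose 3′ UTR holds either 7-mer was chosen after the results were seen, and the other alternatives were fixed before. Nfe2l2 kept its direction under every alternative that gave it a value, and its call in all of these but 1: on the 4 libraries of a line alone its log2 fold changes of −1.91 in PyMT-1099 LT and −1.86 in Py2T LT had adjusted p of 0.46 and 1, with fewer libraries, and in MT∆Ecad the adjusted p was 0.043. With a single library left out its log2 fold change lay between −2.09 and −1.73 in PyMT-1099 LT, between −1.94 and −1.78 in Py2T LT and between −2.01 and −1.93 in MT∆Ecad. The numbers of called genes kept within 1.5 times their value with TMM or median-of-ratios scaling and the robust or untrended variance. Those that moved further elsewhere follow. PyMT-1099 LT had 65 called genes, and 28 and 123 with pseudocounts of 0.25 and 5, 125 without a filter, 36 with a filter at CPM 5, 13 by edgeR, 1125 with the replicate block and 0 on its own 4 libraries. A 2-fold threshold left 11, an adjusted p under 0.01 left 8, and leaving out single libraries gave 7 to 67. Py2T LT had 19, and 10 and 30 with these pseudocounts, 30 without a filter, 12 at CPM 5, 6 by edgeR, 33 by DESeq2, 127 with the block, 7 without genes that hold either 7-mer and 0 on its own 4 libraries. The stricter thresholds left 6 and 5, and single libraries left out gave 5 to 11. MT∆Ecad had 2164, and 5324 with the block, 1116 on its own 4 libraries, 234 and 866 at the stricter thresholds and 576 to 2664 with a library left out. The average had 1532, and 856 by edgeR, 4997 with the block, 2329 with a block by number across lines, 6 and 346 at the stricter thresholds and 660 to 2126 with a library left out. The difference between lines had 273, and 122 and 437 with the pseudocounts, 20 by edgeR, 2377 and 593 with the blocks, 148 and 43 at the stricter thresholds and 29 to 189 with a library left out. Stricter thresholds lower a count by construction. Leaving out a library could also raise it (MT∆Ecad to 2664 and the average to 2126, both without Py2T LT siNrf2 2), and the cause of these and the other changes was not tested. Camera called 13, 10, 16 and 16 lists in PyMT-1099 LT, in Py2T LT, in MT∆Ecad and on the average, and with an estimated correlation 0, 1, 1 and 1. By fry it was 0 in PyMT-1099 LT and 1 in Py2T LT, and with a library left out the 4 counts ran from 9 to 16, 8 to 14, 15 to 17 and 13 to 21. Of the camera calls in these 4 contrasts, fry kept 29 and lost 26. The NRF2 target, S-phase, mitosis, MYC, matrix and interferon lists passed fry both on the average and in MT∆Ecad. The robust variance does not enter camera. The correlation of PyMT-1099 LT with Py2T LT (0.372) was 0.106 by edgeR and 0.139 by DESeq2 and ran from −0.10, without Py2T LT siNrf2 1, to 0.562 with a library left out. That of PyMT-1099 LT with MT∆Ecad (0.469) was 0.211 and 0.246 by these tools, 0.517 with a pseudocount of 5, 0.552 at a mean CPM of at least 10 and 0.331 to 0.487 with a library left out. That of Py2T LT with MT∆Ecad (0.222) was 0.072 and 0.089 by these tools and 0.036 to 0.273 with a library left out, and the cause was not tested. In the fits with a library left out an incomplete pair lets the effect of the replicate number into the fold changes, so they do not measure instability alone. Of 161 called results for named genes other than Nfe2l2, 42 lost their call by edgeR, 21 by DESeq2, 12 with median-of-ratios scaling, 19 without a filter and 14 to 51 with a library left out. Reversed in sign on the average were Cbr3 (0.026 by edgeR and 0.083 by DESeq2), Trp63 (−0.078 by edgeR) and Blvrb (0.002 by DESeq2). With a library left out Hmox1 ran from −0.159 to 0.077, Blvrb from −0.09 to 0.043 and Htatip2 from −0.020 to 0.077. The median of the mitosis genes list, Py2T LT, ran from −0.213 to −0.003, and its test reversed without siNrf2 1 of that line. A CPM of 1 rests on 27.1 to 37.0 reads, which limits the precision of the lowest values.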

Other observations

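The levels of single epithelial and mesenchymal genes in the siCtl libraries follow (mean CPM ± SD, n = 2, for PyMT-1099 LT, for Py2T LT and for MT∆Ecad), with no test between lines. Cdh1 stood at 49.68 ± 2.67, 13.88 ± 1.93 and 0.3929 ± 0.0858, Epcam at 0 ± 0, 17.72 ± 1.45 and 0.06479 ± 0.0916, Krt8 at 1591 ± 147, 1421 ± 176 and 822 ± 73.6 and Krt14 at 13.7 ± 0.916, 32.18 ± 1.53 and 132.2 ± 13.6. Cdh2 stood at 206.2 ± 2.19, 14 ± 0.382 and 215.2 ± 0.1, Vim at 3547 ± 241, 1727 ± 181 and 5011 ± 55.2, Fn1 at 5432 ± 60.1, 9132 ± 740 and 5469 ± 313 and Zeb1 at 62.21 ± 6.96, 76.15 ± 10.6 and 89.67 ± 9.35. Keap1 stood at 55.17 ± 0.036, 74.05 ± 8.59 and 76.41 ± 7.68 and Nfe2l1 at 329.9 ± 17.6, 343.7 ± 11 and 280 ± 18.3.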
